A study of Homo sapiens with 6 samples.

How the data were processed

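Total RNA was extracted with TRIzol from KARPAS-45 cells and sequenced from TruSeq libraries, 3 of control cells and 3 of MEF2C-OE cells, per the labels' protocols. The deposited values were counts of reads per gene, 1 file per library, not normalized, and the authors made them with Trim Galore, STAR and HTSeq on the hg38 build, per the submitters' processing notes. Tool versions, the annotation release, the strand setting and any filters are not given in the sources used here. Each file listed 78932 gene identifiers and 5 summary lines. The summary lines were left out of library sizes and tests. Reads outside annotated features made up 20.9% to 21.8% of the lines' total, ambiguous reads 3.31% to 3.46% and reads without a unique alignment 4.03% to 4.68%, so 70.9% to 71.3% were assigned to genes. Reads that align to several places were therefore not counted, which lowers the values of genes with near-identical copies. In these files 246 of 249 annotated genes wholly inside exons of a same-strand gene of at least 50 CPM had no count, against 56 of 210 inside exons of an opposite-strand gene.

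Samples were grouped by the labels, which call the replicates technical and the control cells wild type. Whether the control cells received a vector or were sorted is not given in the sources used here. Symbols were found for 61481 of the identifiers in a table of gene names, and coordinates, GC content and transcript length were taken from GENCODE 29 (GRCh38), which had GC content and length for 88.8% of the genes tested.

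Counts were analysed in R 4.3.3 with edgeR 4.0.16, using the default count filter (filterByExpr), TMM normalization and a robust quasi-likelihood test of MEF2C-OE against control, with Benjamini-Hochberg adjustment over the 19086 genes that passed the filter. The biological coefficient of variation was 3.67%. A gene was called at an adjusted p under 0.05. Standard errors were obtained from the fold change and the test's F statistic. CPM values were scaled by TMM for tested genes and by library totals for others. A count of 0 was read as up to 3 counts, which corresponds to 0.0527 to 0.0622 CPM in these libraries, and intervals and floors cover counting error only.

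A set of 33 gene lists was written before the data were examined, from general knowledge of T-cell leukaemia, menin and KMT2A biology, MEF2 biology, stress, metabolism, the cell cycle and other cell types. MEF2C was left out of each list. Lists with at least 5 tested genes, 30 in number, were compared with all other tested genes by limma 3.58.1 camera with a preset correlation of 0.01, adjusted over the lists. Of the 30, 11 passed, 7 lower and 4 higher, and 5 passed with an estimated correlation: the immediate early, proliferation, DNA replication, MYC and glycolysis lists. Members were also counted by the edgeR test over all genes and adjusted over the list alone.

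The genes named were set by a rule written before the data were examined. It took 21 fixed genes whatever their values, the 10 of largest rise and the 10 of largest fall among called genes with at least 5 CPM in the higher group, no overlap between the groups and a symbol that is not a clone, antisense, pseudogene or readthrough name, and up to 4 called members of each list with the largest absolute log2 fold change at a mean of at least 1 CPM. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

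The test was checked on simulated counts for the 19086 genes, drawn from the real means and library sizes. It recovered 26, 30, 36 and 48 of 50 genes changed 1.25-, 1.5-, 2- and 4-fold for MEF2C-OE against control, and called 10 of 18886 unchanged genes. Those 10 made up 6.67% of the genes called. This simulation changed 200 genes, far fewer than were called in the data. In a separate simulation, camera called the 1 list of 25 genes lowered 1.3-fold and 0 of 50 unchanged lists. Genes were drawn independently there, so the preset correlation was not checked. In the data the estimated correlation of the ribosomal protein list was 0.284. Alternatives covered the scaling, the count filter, DESeq2 1.42.0, limma-voom, tests against a fold threshold, a replicate block, the removal of each library in turn, and fry, which tests whether the genes of a list move, on balance, one way. A correction for GC content and transcript length was added after the data were seen. It fitted each library's deviation from the mean log2 CPM by splines of 5 degrees of freedom on both properties and entered the fit as an offset in edgeR. Figures were drawn with matplotlib 3.10.9.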

Results

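Gene expression was measured by RNA sequencing in KARPAS-45, a human T-cell acute lymphoblastic leukaemia line that carries a fusion of KMT2A with FOXO4. The 6 libraries formed 2 groups of 3, control cells labelled as wild type and cells that overexpressed MEF2C, a MADS-box transcription factor (MEF2C-OE). The MEF2C-OE cells had received a lentiviral vector with MEF2C under the EF1A promoter, linked to mCherry, and were sorted for mCherry 120 hours after transduction. The libraries held 51198955 to 56405139 reads assigned to genes in the control group and 48218497 to 56890745 in the MEF2C-OE group. The replicates are labelled as technical, so p-values measure only the spread between these libraries. Pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.02 to 4.88, so no pair was taken for 1 library deposited more than once. This does not show that the libraries came from separate cultures, and n counts libraries.

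The comparison asked which transcripts differed once MEF2C was overexpressed, within a study of menin, the KMT2A cofactor encoded by MEN1. MEF2C itself (ENSG00000081189.17, minus strand of chromosome 5, 88717117 to 88904257 in GRCh38) was higher in all 3 MEF2C-OE libraries than in any control library. The gene had 40, 29 and 41 reads in the MEF2C-OE libraries and 10, 1 and 0 reads in the control libraries. These counts correspond to 0.680 ± 0.0730 CPM against 0.0659 ± 0.0982 CPM (SD, n = 3), with a log2 fold change of 3.28 (SE 0.60, adjusted p = 1.5e-05, edgeR quasi-likelihood test). The size of the fold rested on control replicate 1, which held 10 of the 11 control reads, and without it the log2 fold change was 5.83. The ratio of summed reads was 10.1, with an exact 95% interval of 5.41 to 20.7 that covers counting error only. MEF2C ranked 14796 by reads among all genes in the MEF2C-OE libraries, and gene counts do not separate vector transcripts from endogenous ones.

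Across the transcriptome, the MEF2C-OE cells had lower levels of ribosomal protein, glycolysis and immediate early and stress genes, and higher levels of cell cycle, DNA replication and histone genes, by limma camera. The calls of the ribosomal protein and histone lists were lost at adjusted p = 0.126 and adjusted p = 0.195 with an estimated correlation, and 8 of 16 histone genes rose. Most changes were small. Of 19086 genes tested, 3962 rose and 3859 fell (adjusted p under 0.05), with a median size of 1.22-fold among these 7821 genes. At least 2-fold changes were found for 509 genes, 242 higher and 267 lower, and 36 of these had a mean of 5 CPM or more, 22 higher and 14 lower. The groups did not overlap for 9321 of the 19086 genes tested, or 48.8%, where chance gives 10% of unchanged genes. Changes also followed gene composition. Across 10813 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.38 with GC content and 0.30 with transcript length. Within single libraries, the median deviation of genes in the top decile of GC content minus that in the bottom decile was 0.10 to 0.18 (log2) in the control libraries and -0.16 to -0.10 in the MEF2C-OE libraries.

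The genes of largest rise did not belong to a single fixed list. KLHDC7B rose from 2.81 ± 0.715 to 10.0 ± 0.296 CPM (SD, n = 3), a log2 fold change of 1.84 (SE 0.13, adjusted p = 5.4e-16). ANKRD34C rose by 1.78 and FIBCD1, which encodes a chitin-binding receptor, by 1.73. ESRP1, an epithelial splicing regulator, rose from 7.06 ± 0.274 to 22.9 ± 0.880 CPM (log2 fold change 1.70, SE 0.076, adjusted p = 7.3e-22). The extracellular matrix gene HMCN1 rose from 5.19 ± 1.07 to 14.7 ± 1.76 CPM. PLEK, which encodes the haematopoietic protein pleckstrin, rose by 1.35 on the log2 scale and the neuronal gene SLITRK5 by 1.27. KLF15 and ZBTB20, both zinc finger transcription factors, each rose by 1.27, and the non-coding FRG1-DT rose from 19.3 ± 0.426 to 45.8 ± 2.08 CPM.

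**Figure D1:**
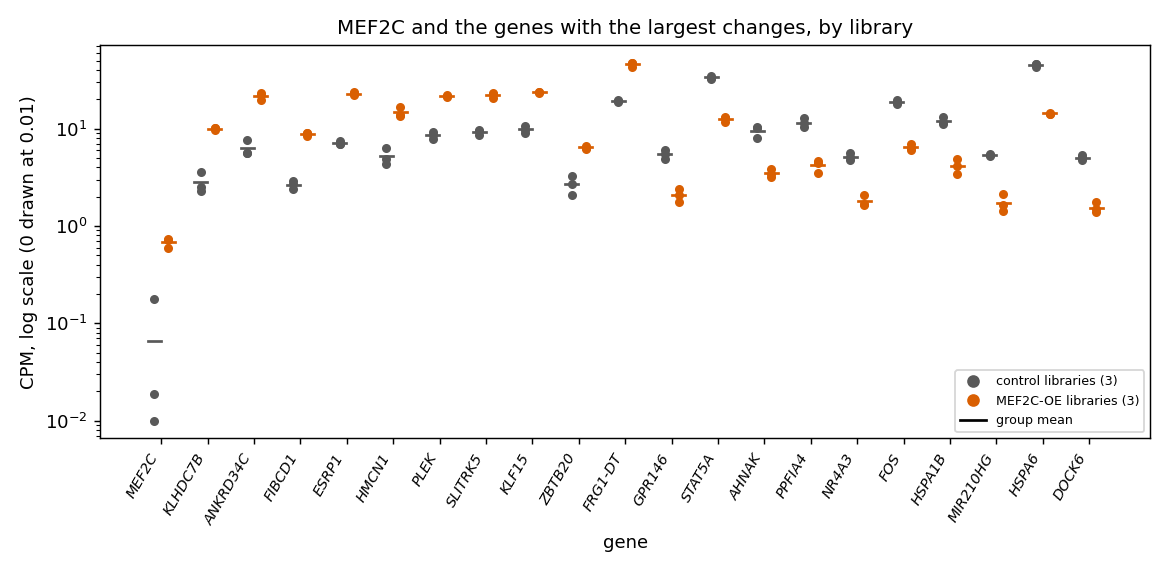
Normalised expression (CPM, log scale, 0 drawn at 0.01) of MEF2C and the 20 genes of largest rise or fall, with 1 point per library, grey for the 3 control and orange for the 3 MEF2C-OE libraries, and a line at each group mean. The groups are separated for each gene, and MEF2C lies below 1 CPM in all 6 libraries.

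Among the largest falls were stress-inducible and signalling genes. The guanine nucleotide exchange factor gene DOCK6 fell from 5.05 ± 0.327 to 1.54 ± 0.185 CPM (SD, n = 3; log2 fold change -1.71, SE 0.16, adjusted p = 2.8e-12). HSPA6, a strictly heat-inducible HSP70 gene, had 43.4 to 45.8 CPM in the control libraries and fell to 14.3 ± 0.0392 CPM (log2 fold change -1.65, SE 0.055, adjusted p = 5.9e-26). MIR210HG, host of the hypoxia-induced microRNA miR-210, had a log2 fold change of -1.63, and PPFIA4, a liprin gene, one of -1.46. STAT5A, a mediator of cytokine receptor signalling, fell from 33.5 ± 1.04 to 12.5 ± 0.854 CPM (log2 fold change -1.42, adjusted p = 7.8e-22). AHNAK, which encodes a large scaffold protein, and the receptor gene GPR146 fell by 1.44 and 1.40 on the log2 scale.

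Immediate early and stress genes, which respond within minutes to mitogens and handling, fell as a group. Of 18 tested, 15 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.61, limma camera adjusted p = 6.47e-08, and adjusted p = 0.0385 with an estimated correlation). FOS fell from 18.7 ± 0.901 to 6.44 ± 0.510 CPM, a log2 fold change of -1.53, and FOSB by 0.98. HSPA1B and HSPA1A fell by 1.54 and 1.49 on the log2 scale, values that are uncertain singly because the copies are nearly identical in sequence. With the GC and length trend removed the median of the list was -0.49. Textbook MEF2 target genes, many of them activity-regulated, did not pass the list test (median -0.49, adjusted p = 0.0539). Of their 15 tested members 8 fell, 2 rose and 5 did not pass, also adjusted over the list alone. The orphan nuclear receptor genes NR4A3 and NR4A1 had log2 fold changes of -1.52 and -1.24, KLF2 had -0.98 and the synaptic gene ARC -1.48. Outside the stress list, 6 of 13 MEF2 targets fell and 2 rose. Only 2 tested members were shared with that list, and NR4A1, NR4A3, KLF2 and ARC stayed among the 13. The count therefore does not separate MEF2 targets from activity-regulated genes. The list passed in 10 of 17 alternative settings, among them the removal of any 1 library other than control replicate 1. The camera adjusted p lay between 3.5e-04, with no count filter, and 0.089 over all 17. Outside those 17, camera with an estimated correlation did not call the list (adjusted p = 0.195), while fry called it lower (adjusted p = 9.18e-05). Genes of the MEF2 family and of class IIa HDACs moved both ways, with 4 of 12 higher, 5 lower and 3 not past the test, and 5 higher and 5 lower adjusted over the list alone (adjusted p = 0.85). MEF2A rose from 137 ± 2.55 to 170 ± 3.22 CPM (log2 fold change 0.31) and the kinase gene SIK2 by 0.39, whereas HDAC7 and HDAC5 fell by 0.39 and 0.42. HDAC9, a MEF2-binding deacetylase gene, had 0.08 (adjusted p = 0.086), and -0.10 with the GC and length trend removed (adjusted p = 0.017). It was called in 3 alternative settings (-0.10 to 0.11), 1 of them with a single library left out, and as higher in all but the corrected one.

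Ribosomal protein genes fell without exception. All 42 tested were lower, also adjusted over the list alone (median -0.49, camera adjusted p = 9.02e-22). The call was lost when the correlation among these genes was estimated (adjusted p = 0.126 with an estimated correlation). RPS2 fell from 1622 ± 86.1 to 994.5 ± 28.3 CPM, and RPS15, RPL12 and RPS12 fell by 0.72, 0.70 and 0.69 on the log2 scale. The list took 4.58% ± 0.107 of reads in the control libraries and 3.33% ± 0.0240 in the MEF2C-OE libraries (SD, n = 3). With the GC and length trend removed its median was -0.42. MYC and ribosome biogenesis genes fell in 20 of 25 cases, with 1 higher and 4 not past the test, and 21 lower adjusted over the list alone (median -0.24, adjusted p = 1.63e-06, and adjusted p = 0.045 with an estimated correlation). MYC fell from 131 ± 3.17 to 105 ± 3.18 CPM (log2 fold change -0.31, adjusted p = 1.3e-11). The nucleolar methyltransferase gene FBL fell by 0.48, NME1 by 0.47 and PPAN by 0.37, whose call was lost with the GC and length trend removed (-0.17).

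Glycolysis genes fell in 20 of 22 cases and 2 did not pass, also adjusted over the list alone (median -0.40, adjusted p = 4.76e-11, and adjusted p = 0.0385 with an estimated correlation). LDHA, which encodes the lactate dehydrogenase A subunit, fell from 661 ± 3.40 to 427 ± 2.18 CPM (log2 fold change -0.63). Hexokinase gene HK2 fell by 0.63, the glucose transporter gene SLC2A3 by 0.75 and ALDOC by 0.62. With the GC and length trend removed the median was -0.31. Nuclear oxidative phosphorylation genes fell in 18 of 26 cases, none rose and 8 did not pass, with 19 lower adjusted over the list alone (median -0.17, adjusted p = 7.86e-05). Their call was lost at adjusted p = 0.195 with an estimated correlation. Examples were the complex I gene NDUFA1 with a log2 fold change of -0.42, COX7A2 with -0.38 and UQCRFS1 with -0.37. Of 13 mitochondrially encoded genes 3 fell and 10 did not pass, with 2 lower adjusted over the list alone (adjusted p = 0.161). These were MT-CO2 at -0.31, MT-CYB at -0.26 and MT-CO1 at -0.13. MT-CO2 and MT-CYB each lost their call in 4 alternative settings, among them the removal of any 1 control library (-0.32 to -0.31 and -0.27 to -0.25), MT-CYB also without MEF2C-OE replicate 1 (-0.27), and MT-CO1 without control replicate 2 (-0.12).

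Cell cycle genes were higher. In the proliferation and mitosis list 17 of 24 rose, 1 fell and 6 did not pass, also adjusted over the list alone (median 0.20, adjusted p = 2.88e-06, and adjusted p = 0.0385 with an estimated correlation). MKI67, the gene of the Ki-67 antigen, rose from 782 ± 5.23 to 1023 ± 8.99 CPM (log2 fold change 0.39, adjusted p = 7.7e-20). The kinetochore motor gene CENPE rose by 0.58, HMMR by 0.55, ASPM by 0.49 and the transcription factor gene FOXM1 by 0.47. DNA replication genes rose in 21 of 26 cases, with 1 lower and 4 not past the test, also adjusted over the list alone (median 0.15, adjusted p = 2.88e-06, and adjusted p = 0.0385 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, rose by 0.46, the licensing factor CDT1 by 0.36, CHAF1A by 0.35 and RFC2 by 0.33. Replication-dependent histone genes rose in 8 of 16 cases, with 1 lower and 7 not past the test, also adjusted over the list alone (median 0.40, adjusted p = 0.00319). These 16 were the tested genes of 20 found, and their median level in the control libraries was only 6.61 CPM. Their call was lost at adjusted p = 0.195 with an estimated correlation. H2BC18 rose by 0.91, H2BC4 by 0.71, H2AC11 by 0.63 and H3C2 by 0.52. H3C2 lost its call in 7 alternative settings (0.33 to 0.55), among them the removal of any 1 library other than MEF2C-OE replicate 3. With the GC and length trend removed, the medians of the mitosis, replication and histone lists were 0.18, 0.21 and 0.45.

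Genes of the T-cell receptor complex and its proximal signalling fell in 18 of 22 cases, with 3 higher and 1 not past the test, also adjusted over the list alone (median -0.25, adjusted p = 7.17e-05). The call was lost at adjusted p = 0.191 with an estimated correlation, and the median with the GC and length trend removed was -0.20. The adaptor gene LAT fell from 10.7 ± 0.843 to 4.48 ± 0.702 CPM and TRGC2 by 0.51 on the log2 scale, while FYN rose by 0.50 and TRAT1 by 0.56. T-cell differentiation genes moved both ways, with 7 of 26 higher, 10 lower and 9 not past the test, also adjusted over the list alone (adjusted p = 0.158). GATA3, a master regulator of T-lineage cells, fell from 296 ± 3.80 to 186 ± 7.43 CPM (log2 fold change -0.67, adjusted p = 6.6e-24). CD2, the terminal transferase gene DNTT and CD38 fell by 0.68, 0.52 and 0.44. The recombinase gene RAG1 had a log2 fold change of 0.80 at 0.672 ± 0.191 against 1.19 ± 0.523 CPM (adjusted p = 0.035), and lost its call in 5 alternative settings, among them the removal of control replicate 3 (0.59) or MEF2C-OE replicate 2 (0.39). CD7 had -0.03 (adjusted p = 0.57), and 0.16 with the GC and length trend removed (adjusted p = 5.4e-04). NOTCH1 target genes fell in 8 of 19 cases, with 3 higher and 8 not past the test, and 9 lower and 4 higher adjusted over the list alone (adjusted p = 0.174). NOTCH1, the receptor gene often mutated in this leukaemia, fell by 0.18 on the log2 scale, its target HES1 by 0.44, NFKB2 by 0.63 and CISD3 by 0.26, whose call was lost without control replicate 3 (-0.18) and with the GC and length trend removed (-0.12).

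In the menin and KMT2A lists the changes were modest. MEN1 fell from 71.9 ± 0.347 to 60.9 ± 0.730 CPM (SD, n = 3; log2 fold change -0.24, SE 0.036, adjusted p = 4.2e-07) and KMT2A rose from 133 ± 3.41 to 177 ± 2.80 CPM (0.41, SE 0.027, adjusted p = 1.8e-16). FOXO4 had -0.06 (adjusted p = 0.29), and reads of the fusion cannot be separated from those of either gene. Of 16 complex members and partners 7 rose, 4 fell and 5 did not pass, with 8 higher adjusted over the list alone (adjusted p = 0.174). PSIP1, which encodes the tethering protein LEDGF, rose by 0.46 and KMT2B fell by 0.23. Of 28 target genes of KMT2A fusions and menin 12 were tested, and the others had at most 15 counted reads in any library. Of the 12 tested, 7 rose, 1 fell and 4 did not pass, also adjusted over the list alone. The list median was 0.13 (camera adjusted p = 0.0378, and adjusted p = 0.195 with an estimated correlation). CDK6, a G1 cyclin-dependent kinase gene, rose from 999.3 ± 14.7 to 1271 ± 18.9 CPM, PBX3 and JMJD1C each rose by 0.29 and ARID2 by 0.27, whereas the homeobox gene MEIS1 fell from 156 ± 2.81 to 144 ± 0.895 CPM (log2 fold change -0.12). The call of this list ended in 6 of 17 alternative settings, over which adjusted p ranged from 0.0025 to 0.88. Among the 6 were the GC and length trend removed (median 0.01, adjusted p = 0.88), no count filter (adjusted p = 0.23), a filter of 1 CPM (adjusted p = 0.074) and the removal of control replicate 1 (adjusted p = 0.077) or MEF2C-OE replicate 1 (adjusted p = 0.06). HOXA9 and HOXA10, the usual targets of KMT2A fusions, had 0 counted reads in all 6 libraries. Their annotated positions overlap on the same strand (chromosome 7, 27162435 to 27175180 and 27170591 to 27180261 in GRCh38), where reads can be left uncounted as ambiguous, so these zeros set no upper limit on expression.

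Of 24 genes of early T-precursor and immature leukaemia 8 were tested, and the others had at most 12 counted reads in any library. Of the 8 tested, 5 rose, 1 fell and 2 did not pass, also adjusted over the list alone (median 0.23, camera adjusted p = 0.0809). BCL2, an inhibitor of apoptosis, rose from 104 ± 2.52 to 126 ± 2.65 CPM (log2 fold change 0.28), the receptor gene KIT by 0.24, ZEB2 by 0.23 and RUNX1 by 0.22. ZEB2 lost its call with the GC and length trend removed (0.04). LYL1, a further gene of this list, had 0.329 ± 0.108 against 0.343 ± 0.165 CPM (log2 fold change 0.04, adjusted p = 0.96). LMO2, HHEX, SPI1 and CD34 had between 0 and 10 reads in each library and were not tested. In the BCL2 family 5 of 14 genes rose, 4 fell and 5 did not pass, also adjusted over the list alone (median -0.06, mean 0.07, adjusted p = 0.897). BCL2L11, which encodes the pro-apoptotic BIM, rose by 0.43 and BMF by 0.38, while BAX fell by 0.38. Among p53 target genes 4 of 20 rose, 8 fell and 8 did not pass, also adjusted over the list alone (adjusted p = 0.158), with CDKN1A higher by 0.39 and PLK3 and TP53INP1 lower by log2 fold changes of -0.49 and -0.34.

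Cytoskeleton and adhesion genes fell in 17 of 26 cases, with 3 higher and 6 not past the test, also adjusted over the list alone (median -0.32, adjusted p = 3.74e-04). Their call was lost at adjusted p = 0.0623 with an estimated correlation, and the median was -0.19 with the GC and length trend removed. The actin gene ACTG1 fell from 1082 ± 14.8 to 655 ± 15.5 CPM (log2 fold change -0.72), LGALS1, which encodes galectin-1, by 1.79 and ZYX by 0.69. Chemokine and cytokine receptor genes fell in 9 of 21 cases, with 4 higher and 8 not past the test, and 5 higher adjusted over the list alone (adjusted p = 0.273). CCR9, the thymus- and gut-homing receptor gene, fell from 97.3 ± 1.60 to 52.9 ± 1.44 CPM (log2 fold change -0.88), IL4R by 0.49 and IL2RG by 0.40, and IL6ST rose by 0.41. Of 13 NF-kB target genes 4 fell, 1 rose and 8 did not pass, also adjusted over the list alone (adjusted p = 0.171), with TRAF1 at -1.08, BCL3 at -0.84 and BIRC3 at 0.48. In the unfolded protein and integrated stress response list 11 of 20 rose, 6 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.158). The cystine transporter gene SLC7A11 rose from 94.9 ± 2.14 to 207 ± 1.11 CPM (log2 fold change 1.13, adjusted p = 1.9e-30), CHAC1 by 0.91 and the pseudokinase gene TRIB3 by 0.69, whereas SDF2L1 fell by 0.75.

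Interferon-stimulated genes moved both ways, with 8 of 26 higher, 6 lower and 12 not past the test, also adjusted over the list alone (median 0.06, mean -0.02, adjusted p = 0.742). RSAD2 rose by 0.73, and IFI6, BST2 and ISG15 fell by 0.67, 0.63 and 0.49. Of 15 genes of MHC class I presentation 5 rose, 7 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.674). HLA-E fell by 0.39, and HLA-B and HLA-C by 0.32 and 0.27, although reads among these related genes can be shared, and PSMB10 by 0.44. HLA-B and HLA-C lost their calls with the GC and length trend removed (-0.14 and -0.08). Of 4 tested MHC class II genes, HLA-DMA fell by 0.63 and 3 did not pass, also adjusted over the list alone, and the call of HLA-DMA was lost without control replicate 2 (-0.55) or 3 (-0.50). In cholesterol biosynthesis 8 of 20 genes rose, 4 fell and 8 did not pass, with 6 lower adjusted over the list alone (adjusted p = 0.702), among them SREBF2 at 0.25, TM7SF2 at -0.46 and HSD17B7 at -0.42.

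Of the lists of markers of other cell types, the 4 that could be tested did not pass camera, while fry called the B-cell (adjusted p = 0.0313) and stromal lists (adjusted p = 6.06e-04) lower. Of 28 myeloid markers 7 were tested, of which 2 rose, 2 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.905). CEBPB rose by 0.63 and CEBPA by 0.52, while CTSS and VCAN fell by 0.96 and 0.16. Of 7 B-cell markers 1 rose, 3 fell and 3 did not pass, also adjusted over the list alone (adjusted p = 0.594), with POU2AF1 at 0.62, BLK at -0.60, CD79B at -0.56 and CD72 at -0.36. CD79B lost its call in 11 alternative settings (-0.63 to -0.36), among them the removal of any 1 library other than control replicate 1, and CD72 in 4 (-0.33 to -0.23), among them the removal of control replicate 1 or 3 or MEF2C-OE replicate 3. Of 6 NK and cytotoxic markers 1 rose and 5 did not pass, and 0 rose adjusted over the list alone (adjusted p = 0.834). Of 2 erythroid and megakaryocyte genes, ITGA2B fell by 1.63 and 1 did not pass, also adjusted over the list alone. Of 6 stromal and endothelial genes 2 fell and 4 did not pass, also adjusted over the list alone (adjusted p = 0.0809), PDGFRB from 4.14 ± 0.576 to 0.812 ± 0.213 CPM (log2 fold change -2.36), and COL1A1 with a log2 fold change of -0.83. Of 3 markers of HEK293T, the line in which the vector was packaged, CDH2 rose by 0.10 and 2 did not pass, also adjusted over the list alone, and the call of CDH2 was lost without MEF2C-OE replicate 1 (0.07) and with the GC and length trend removed (0.06). The lists of erythroid, HEK293T and MHC class II genes had too few tested members for a list test.

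**Figure D2:**
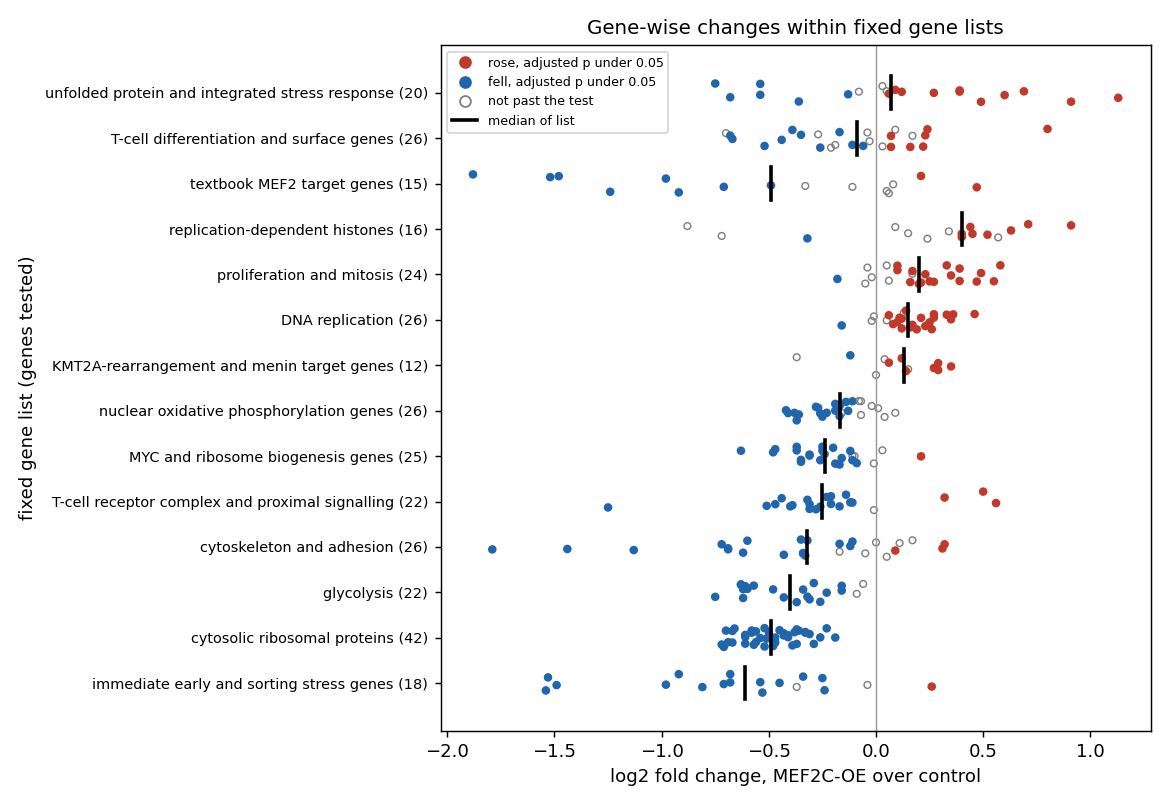
Log2 fold change of MEF2C-OE over control (horizontal axis) for each tested member of the 11 fixed gene lists that passed the list test and of 3 further lists (vertical axis, number of tested genes in brackets), with red points for genes that rose, blue for genes that fell, open grey circles for genes not past adjusted p 0.05, and a black bar at the list median. All 42 ribosomal protein genes lie below 0, and the immediate early list has the lowest median, -0.61.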

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

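The test for a mislabelled sample, the list of hypoxia-induced genes, the correction for GC content and transcript length and the rule that leaves overlap with MEF2C open were chosen after the results were seen. Reads outside annotated features, which enter no comparison, made up 21.54% ± 0.22 of the total in the MEF2C-OE libraries and 21.04% ± 0.19 in the control libraries (SD, n = 3), and each MEF2C-OE library lay above each control library (2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The groups also did not overlap in ambiguous reads (3.316% ± 0.0137 in MEF2C-OE against 3.443% ± 0.0232 in control libraries). Reads without a unique alignment were likewise separated, at 4.041% ± 0.0118 against 4.456% ± 0.222. Whether these differences bear on genes with near-identical copies was not tested.

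Many small changes separated the groups. With each library's trend on GC content and transcript length removed, 7261 genes passed against 7821 without the correction. Of the 7821, 5939 were called both times, 5856 of them in the same direction, and 1882 calls were lost, so the trend is not the whole cause but may account for part of the small changes. Among 132 stretches of 20 Mb, the largest median log2 fold change relative to the genome was -0.17. That argues against a copy number difference that spans such a stretch in most cells. A shorter difference, or one in a minority of cells, could be missed by these medians and stays open. Only 1 of the 10 splits of the 6 libraries gave as many genes by edgeR, the real one with 7821 against at most 0 in the others. Each other split mixed control and MEF2C-OE libraries, so the difference between them widened the spread within groups and lowered the calls. In addition, 10 splits are too few for a share under 0.05, so the splits decide nothing. MEF2C, transduction, sorting and separate culture stay open because each coincides with the groups.

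MEF2C had few reads for a gene driven by a strong promoter. No library lay within the MEF2C range of the other group. The gap between the lowest MEF2C-OE and the highest control library was 0.418 CPM, above the larger SD of 0.0982 CPM. These values had been seen before the rule for a mislabelled sample was written, so its outcome was known and it decides nothing by itself. In GENCODE 29, 13.1% of MEF2C coding bases lie in exons of another gene. A share under 50% was set beforehand as the bound against a loss of reads to overlap, but that bound holds only for the annotation used for counting, and 21576 of the 78932 identifiers in the files have no position in GENCODE 29, so a loss of reads to overlapping genes of the annotation used for counting stays open. A low vector transcript level or a vector sequence that the aligner could not place was not tested and stays open, as does the biological explanation that MEF2C was overexpressed at this low level.

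Ribosomal protein and glycolysis genes fell together. With the GC and length trend removed their median log2 fold changes were -0.42 and -0.31, which argues against composition bias as the whole cause. Under 4 scalings of the libraries the highest of their medians was -0.38. These scalings differed little, with medians of -0.51 to -0.476 for ribosomal protein genes and -0.412 to -0.377 for glycolysis. Each holds most genes or the read total fixed, so the fall is relative to other genes. A change in total RNA per cell was not tested. If the MEF2C-OE culture was less hypoxic, other hypoxia-induced genes should fall too, and in a list of 23 outside glycolysis 15 fell, 3 rose and 5 did not pass (median -0.26, camera adjusted p = 8.4e-04, and adjusted p = 0.033 with an estimated correlation). That leaves a culture difference as a candidate explanation for the glycolysis genes. Whether a less hypoxic culture would also lower ribosomal protein genes was not tested. Within the hypoxia list VEGFA, RORA and ERO1A, named after their values were seen, rose by 0.54, 0.27 and 0.21. An effect of MEF2C was not separated from the culture.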

How the results depend on the processing

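The GC and length correction was chosen after the data were seen. The count of 7821 genes stayed between 7261 and 7839 under the other scalings, filters, tools and the correction, and the share of higher genes between 46.9% and 55.3%. A test against 1.2-fold left 1940 genes, because it asks for a larger change. Against 509 genes changed at least 2-fold, the count was 159 with a filter of 1 CPM in 3 libraries, which tests fewer low genes, and 201 passed a test against 1.5-fold. Of 30 lists, 5 passed with an estimated correlation against 11, and 24 with fry, which does not compare a list with other genes. Leaving out each library in turn gave 6898 to 7425 genes, 463 to 513 at least 2-fold, 10 to 14 lists, and 2.73 to 5.83 for MEF2C, the highest without control replicate 1. MEF2C was too low for the filter of 1 CPM. Replicate numbers did not pair the samples (correlations of 0.026, -0.041 and -0.029 between deviations of same-numbered libraries), and the fit with a replicate block gave 7798 genes, 513 at least 2-fold, 10 lists and 3.47 for MEF2C. The KMT2A and menin target list alone lost its call there (adjusted p = 0.055). LYL1, not called, reversed to -0.07 with limma-voom and without 4 of the 6 libraries in turn, with a range of -0.25 to 0.40. With the GC and length trend removed FOXO4 reversed to 0.04 without a call, and CD7 to 0.16 and HDAC9 to -0.10, both called then (adjusted p = 5.4e-04 and 0.017). The cause was not tested beyond that construction. HDAC9 was also called higher in other settings, 1 of them with a single library left out (up to 0.11). Of 132 called genes named, 118 kept direction and call in each setting that gave them a value. The other 14 lost calls without changing direction, CD79B in 11 settings (5 of them single libraries left out), H3C2 in 7 (5), RAG1 in 5 (2), CD72 and MT-CO2 in 4 (3 each), MT-CYB in 4 (4), HLA-DMA in 2 (2), CISD3 and CDH2 in 2 (1 each) and MT-CO1 in 1 (1), and ZEB2, HLA-B, HLA-C and PPAN only with the GC and length trend removed (0.04, -0.14, -0.08 and -0.17). DESeq2 called 7387 genes and left the adjusted p of 741 undefined. A count of 0 leaves levels below about 0.06 CPM open. The count filter also left some genes above that level untested. An example, chosen after its values were seen, is RAG2 with 8, 26 and 16 reads in the MEF2C-OE libraries.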

Other observations

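The 6 further lists were chosen after the main results were seen. The lists left out genes already seen to change, except TXNDC5, and their members are named after their values were seen.

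The integrated stress response moved apart from the chaperones of the endoplasmic reticulum. In a list of 22 amino acid response genes, targets of the transcription factor ATF4, 19 rose, 2 fell and 1 did not pass (median log2 fold change 0.38, limma camera adjusted p = 1.24e-08, and adjusted p = 0.0159 with an estimated correlation). The glycine transporter gene SLC6A9 rose by 0.99, the tRNA synthetase gene WARS1 by 0.63, PCK2 by 0.62 and SLC7A1 by 0.49, while DDIT4 and PYCR1 fell by 0.83 and 0.37. Of 19 chaperone and secretory genes 5 rose, 8 fell and 6 did not pass (median 0.02, adjusted p = 0.407), with MANF and CRELD2 at -0.68 and -0.47 and TXNDC5 at 1.00. The medians of the 2 lists differed by 0.37 (2-sided permutation p = 8.2e-04 over genes, which are not independent), so the amino acid limb alone may have been more active in the MEF2C-OE cells, a hypothesis that does not separate MEF2C from the supply of amino acids in the culture.

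The fall of ribosomal protein genes extended to other mRNAs with a 5' terminal oligopyrimidine tract. Of 19 such translation factor and related genes 18 fell and 1 did not pass (median -0.34, camera adjusted p = 2.14e-09, and adjusted p = 0.0145 with an estimated correlation), among them RACK1 at -0.46, EEF1A1 and EIF3F at -0.42 and EEF2 at -0.27. A shared control of these mRNAs may thus be lower in the MEF2C-OE cells, which is a hypothesis only, as their stability and translation were not measured.

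Heat shock factor targets outside the HSP70 genes fell in 13 of 16 cases, with 1 higher and 2 not past the test (median -0.24, camera adjusted p = 5.75e-05), with SERPINH1 at -0.77, HSP90AB1 at -0.57 and HSPE1 at -0.50. A lower output of the ERK pathway may accompany the fall of immediate early genes, since 6 of 12 other ERK output genes fell, 1 rose and 5 did not pass (median -0.15, camera adjusted p = 0.0305), with SPRY4 at -0.80 and ETV4 at -0.96. That call was lost at adjusted p = 0.196 with an estimated correlation.

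ITM2A, a gene on chromosome X (79360384 to 79367667 in GRCh38) that encodes a membrane protein of activated T cells, was chosen after its values were seen. It had 0 reads in each control library and 23, 17 and 18 reads in the MEF2C-OE libraries, or 0.363 ± 0.0527 CPM by library totals (SD, n = 3), at least 6.2-fold higher against the highest floor of a control library (3 counts per library). It was the 1 gene with at least 10 reads in each library of one group and none in the other, and 0 genes had the opposite pattern.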
